A study of Mus musculus with 9 samples.

How the data were processed

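RNA-seq was performed on macrophages sorted from mouse skin wounds, with 4 libraries from day 4 and 5 from day 14 after injury. Per the labels' protocols, wound tissue was digested with enzymes and dispersed mechanically, the cells were stained for CD45, CD11b, F4/80 and CD115, dead cells were excluded with 7-AAD, and libraries were made from Trizol-extracted total RNA with the Illumina TruSeq RNA kit v2 and sequenced as paired ends. This kit does not mark the strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. Per the submitters' processing notes, CASAVA 1.8, HISAT2 2.1.0, SAMtools 1.4, Partek 6.6 and DESeq2 were used with the mouse build mm10. The role of each tool, the gene annotation and filters are not stated.

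The authors deposited a table of estimated counts for 18303 gene symbols in 9 libraries, not normalized. The values are estimated and not plain counts because a mean of 17.2% of them per library are not whole numbers. They were rounded to whole numbers before use. The authors also deposited a table of normalized values for 13673 of these genes, whose unit is a signal on the scale of counts divided by 1 factor per library, with zeros written as 1. Among values of over 50 counts, 82 in the 8 other libraries than day 14 replicate 5 lay more than 2% from that factor. That table was used only to look at how it treats 1 library: of 1072 genes there that lie beyond the point where the counts of day 14 replicate 5 stop, 886 were written as 1 in that library and 186 had been given another value, with a median of 0.981 times the mean of the 8 other libraries. All tests used the estimated counts. The columns were matched to samples by the sample numbers in their headers, and all columns were used.

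Gene positions came from a table of NCBI RefSeq genes on GRCm38.p6, the assembly that mm10 also names. By symbol, 17103 genes matched, 1106 more by an older name and 94 did not. The symbols are printed as in the deposited table. Along the order in which chromosome 10 follows chromosome 1, the counts of day 14 replicate 5 end within the gene Aplp2 on chromosome 9. The test planned before the data were examined used all genes and all 9 libraries and was kept as the main result. It hides changes of 1504 genes, that gene and those beyond it, and pulls them towards lower values at day 14, since 1 of the 5 day 14 libraries holds almost no counts for them. It also calls fewer of the other genes. With the 1504 genes left out, 1956 of 12297 genes were called higher and 1856 lower, against 1713 and 1694 of 13363 with them. The adjusted p-values printed for other genes come from the fit with them. Single-gene values for the 1504 genes were taken from a fit without that library.

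Libraries were scaled with TMM and genes with low counts were removed with filterByExpr. Differences were tested with edgeR 4.0.16 (glmQLFit with robust dispersion and glmQLFTest, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. CPM values are TMM-scaled. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, for lists with at least 5 tested members, with adjustment over 31 lists. Of 21 gene lists and 13 cell type marker lists fixed before the data were examined, 20 and 11 had enough members. The list of mitochondrially encoded transcripts had 0 members tested, and the B cell and adipocyte lists had 2 each. Some members are held by cells of other lists too, so a marker list is no measure of a cell share.

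Genes named in the text follow a rule fixed before the data were examined. It takes the 10 largest changes each way among genes with an adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between days, leaving out predicted genes. It adds the genes of the 3 sort markers, the 3 members with the lowest p and the most abundant member of each gene list, and the 2 most abundant members of each marker list. Of these 122 genes, 101 were followed through the alternatives, a selection made after the values were seen. Members named because 5 or fewer of a list passed in 1 direction or because they lie beyond the break, and Aplp2, Prdm10, Hspa1a, Flt3, Fscn1 and Kmo, were chosen after their values were seen.

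Alternatives planned before the data were examined were RLE, upper-quartile and total-count scaling, the Wald test of DESeq2 1.42.0, limma-voom, no low-count filter, a filter of 5 CPM in at least 4 libraries, non-robust dispersion, log10 library size as a covariate, leaving out each library in turn, camera with an estimated correlation, fry and a prior count of 0.5. Alternatives added after seeing the data were leaving out the genes beyond the break or taking them from the 8 other libraries, the 6 shallower or the 3 deeper libraries alone, and the mean log2 CPM of fibroblast or neutrophil markers as a covariate. No batch or pairing is given in the labels.

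The functions were tested on simulated counts for the comparison of day 14 with day 4, drawn from the real means, dispersions and library sizes, with 200 genes changed among 13198 fitted. Of 99 genes with a simulated log2 change of 1, 56.6% were recovered, and of 95 with a change of 2, 83.2%, while 6 unchanged genes were called. These shares do not give the recovery in the real data. There 3407 genes were called, which moves the adjusted threshold, and the simulated dispersions included day 14 replicate 5. A simulated list of 20 genes with a log2 change of 0.6 was called, and 0 of 19 unchanged lists were. The simulated genes varied independently, so these list counts give no rate of false calls for the real lists, where the median estimated correlation was 0.232. Depth, at 17982630 to 57809914 counts, and 4 or 5 libraries per group limit the precision. Genes that do not pass are not shown to be equal.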

Results

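RNA was sequenced from macrophages sorted from skin wounds of C57BL/6J wild-type mice at 2 times after injury. The cells were gated on CD45, a marker of blood-derived cells, and on CD11b and F4/80, surface proteins of macrophages. The day 4 group held 4 libraries and the day 14 group held 5 libraries. Total counts per library, in the order of the replicates, were 26479011, 27381276, 50162700 and 57809914 at day 4 and 50445159, 25073554, 23713900, 21396799 and 17982630 at day 14. Between 14537 and 16233 of the 18303 listed genes held a count in each library. Nothing in the labels says that the libraries came from separate animals, so the p-values measure the spread between these samples, which may be technical. No pair of libraries of the same day agreed within sampling noise (chi-square per degree of freedom from 11.6 to 79.3), so none was treated as a copy of another, which says nothing about separate animals.

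The counts of day 14 replicate 5 stopped partway along the genome. Of the genes of chromosome 9 with at least 50 counts in each of the 8 other libraries, 0 of the 103 up to the gene Aplp2 (chromosome 9, 31149557 to 31211848, GRCm38) were at 0 in this library. All 483 beyond Aplp2 were at 0. Aplp2 itself held 3082 counts against 9781 counts computed from the 8 other libraries. On the same criterion, 319 of 321 genes of chromosome X and 4 of 4 of chromosome Y were at 0. In total, 808 well-counted genes were at 0 in this library alone, against 0 such genes in any other library. Aplp2 itself, the genes of chromosome 9 from Prdm10, the next well-counted gene, onward, those on X and Y and a few of unknown position made up 1504 genes. Together, these 1504 genes held a mean of 7.55% of the counts in the 8 other libraries and 0.0254% in this one, the 3082 counts of Aplp2 included. They are called the genes beyond the break in what follows, and values given for single genes among them come from the 8 other libraries.

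**Figure D1:**
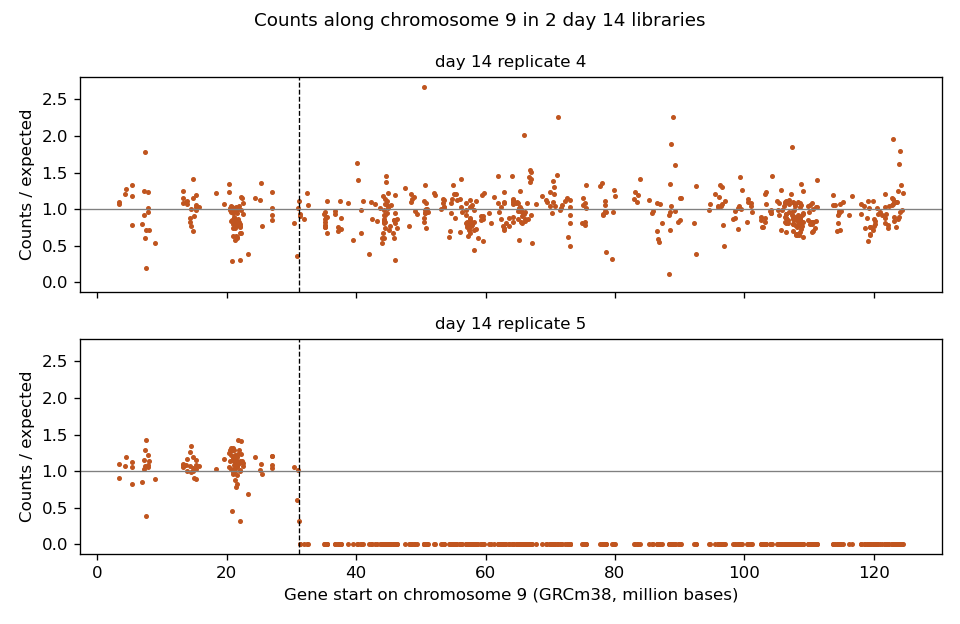
Counts of each well-counted gene divided by the counts computed from the other libraries (vertical axis, no unit) against the gene's start on chromosome 9 (GRCm38, megabases), in day 14 replicates 4 and 5. Each point is a gene, the horizontal line marks a ratio of 1 and the dashed line marks the start of Aplp2, beyond which all 483 genes lay at 0 in replicate 5.

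The study compared early with late wound macrophages. In the RNA of the sorted cells, Arg1, Nos2 and most of the hypoxia-induced and glycolysis genes tested were lower at day 14, and Retnla, Ear2, Mgl2 and most of the MHC class II and cell cycle genes tested were higher. In the same libraries, 11 of 16 fibroblast markers were lower and 7 of 11 dendritic cell and 3 of 5 eosinophil markers higher. With genes beyond the break taken from the 8 other libraries, 8 of 11 and 4 of 5 of the latter were higher. Camera with an estimated correlation called 0 of 31 lists (lowest adjusted p = 0.133). Retnla, which encodes a secreted protein induced by IL-4, rose from 105 ± 27.8 to 2190 ± 477 CPM (counts scaled to a common library size; mean ± SD, n = 4 and 5), a 20.8-fold difference. Arg1, the arginine-degrading enzyme arginase 1, fell from 864 ± 208 to 26.8 ± 27.3 CPM, 32.3-fold lower at day 14 (log2 fold change -5.01, and -5.76 without day 14 replicate 4, which held 70.3 CPM). Saa3, an acute-phase serum amyloid A protein, fell 77.2-fold, from 136 ± 44.7 to 1.76 ± 0.58 CPM.

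Of 13363 genes tested with edgeR's quasi-likelihood test, 1713 were higher and 1694 were lower at day 14 with a Benjamini-Hochberg adjusted p under 0.05. Among these, 561 were at least 2-fold higher and 513 at least 2-fold lower. The calls made up 25.5% of the genes tested, and the counts of list members given below are to be read beside this share. Without day 14 replicate 5, the test called 1967 genes higher and 1836 lower. With the genes beyond the break taken from the 8 other libraries, it called 2144 higher and 1988 lower. Of the 1055 tested genes beyond the break, 25 were called with all 9 libraries (2 higher and 23 lower), and 313 of 1056 were called with 8 (186 higher and 127 lower). Among the 6 shallower libraries (2 at day 4 and 4 at day 14, from 17982630 to 27381276 counts), 668 genes were called higher and 666 lower. Of the 3407 genes called with all 9 libraries, 3406 were also tested there, and 1249 kept their call. All 3406 kept their direction, which is no independent check, since these 6 libraries are among the 9 that called the genes. With the mean log2 CPM of fibroblast markers as a covariate, 470 of the 3407 kept their call and 3360 their direction. Of 83 called genes followed through the alternatives, 17 lost their call in the shallower libraries and 40 with this score. Their median standard error went from 0.16 to 0.21 and 0.27, and their log2 fold changes were a median of 1.01 and 0.941 times those without the change. Upper-quartile scaling raised the share of higher genes among the calls from 50.3% to 65.5% (2064 higher and 1089 lower).

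The genes named by size of change were picked among those that passed the test with no overlap between the libraries of the 2 days. Besides Retnla, the risen genes included Ear2, an eosinophil-associated ribonuclease of a family of near-identical copies, at 13.9 ± 1.73 and 277 ± 39 CPM (log2 fold change 4.31 ± 0.15 SE, adjusted p = 4.78e-07). Cd226, an adhesion receptor of lymphocytes and myeloid cells, rose from 7.99 ± 0.849 to 112 ± 21.5 CPM (log2 fold change 3.80 ± 0.17, adjusted p = 1.26e-06). Ehf, an epithelial transcription factor, and Mucl1, a mucin-like gene, rose 34.5-fold and 64.2-fold, to 27.9 ± 10.3 and 13.1 ± 4.08 CPM. Igj, the immunoglobulin joining chain of antibody-secreting cells (now Jchain), reached 5.72 ± 2.87 CPM from 0.109 ± 0.125 CPM. Upb1, an enzyme of pyrimidine breakdown, rose 32.6-fold. Among the genes that fell, the platelet basic protein gene Ppbp went from 87.0 ± 4.96 to 8.11 ± 1.66 CPM (log2 fold change -3.43 ± 0.14, adjusted p = 9.17e-07). The sodium/proton exchanger gene Slc9b2 fell 61.9-fold and the matrix glycoprotein gene Tnn fell 23.0-fold. Nos2, the inducible nitric oxide synthase, fell 22.4-fold, from 70.4 ± 41.5 to 3.13 ± 3.64 CPM, with day 14 replicate 3 at 9.48 CPM and the others at 0.646 to 2.79 CPM. The prostaglandin E synthase gene Ptges fell 12.3-fold, the neutrophil-attracting chemokine gene Cxcl5 11.9-fold and the apolipoprotein gene Apoc2 8.85-fold. Arg1 and Nos2 had the largest standard errors among these (log2 fold changes -5.01 ± 0.97 and -4.48 ± 0.89, adjusted p = 0.00893 and 0.0098), and both missed the threshold in the 6 shallower libraries (log2 fold changes -4.87 ± 1.11 and -4.56 ± 1.4, adjusted p = 0.0747 and 0.141) and with the fibroblast score (-4.92 ± 1.72 and -4.56 ± 1.56, adjusted p = 0.204 and 0.197), where the standard errors were larger. With this score, Cxcl5 went from -3.57 ± 0.54 to -2.15 ± 0.81 (adjusted p = 0.225) and Igj from 5.51 ± 0.74 to 3.76 ± 0.99 (adjusted p = 0.082), where the change was smaller too, and Ptges missed the threshold at -3.36 ± 0.74 (adjusted p = 0.0611). Tnn, Ehf, Upb1, Mucl1 and Slc9b2 passed with the score, but went from -4.52 to -3.45, from 5.11 to 4.23, from 5.03 to 4.21, from 6.00 to 5.36 and from -5.95 to -6.70. In the shallower libraries, Upb1 was at 6.56, Mucl1 at 5.13 and Cxcl5 at -4.16, and all 3 passed. The log2 fold change of Arg1 was -5.76 without day 14 replicate 4 and that of Nos2 was -5.49 without day 14 replicate 3. Those of Mucl1 and Igj went from 6.00 to 6.66 without day 4 replicate 1 and from 5.51 to 6.72 without day 4 replicate 4.

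**Figure D2:**
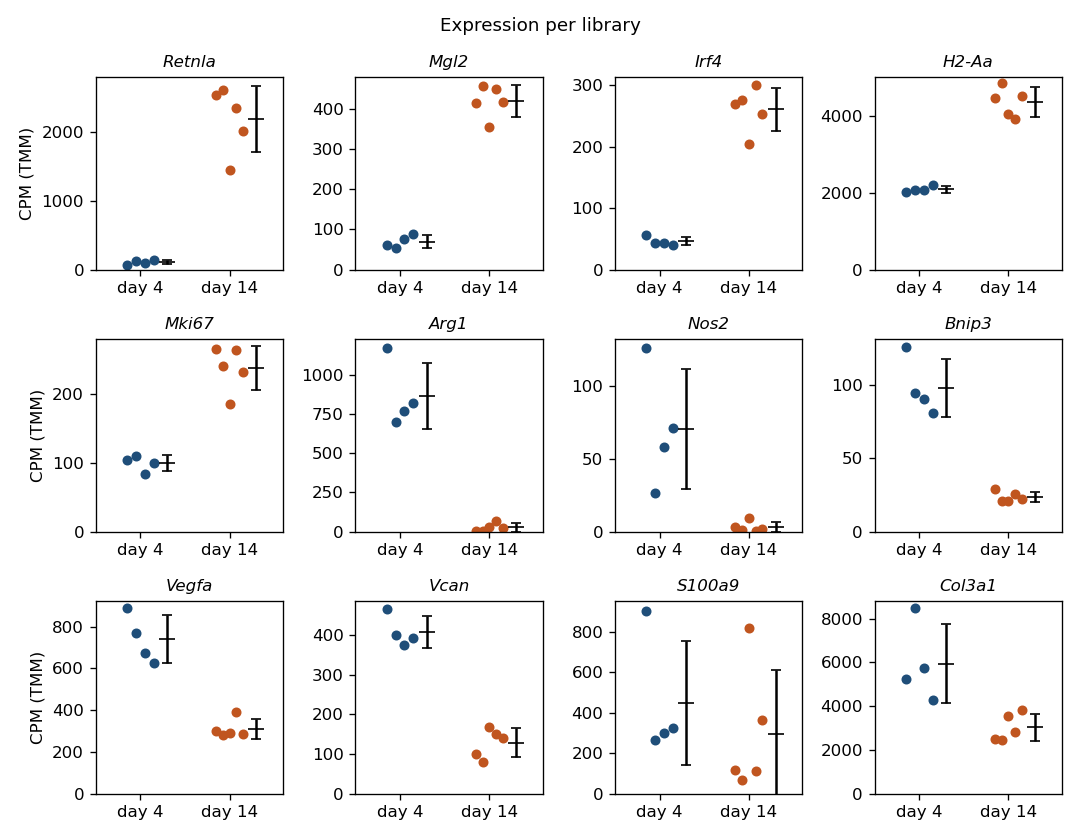
Expression of 12 genes in CPM after TMM scaling (vertical axes, linear, starting at 0) in each day 4 library (blue, 4 points) and each day 14 library (orange, 5 points), with bars for mean ± SD. Retnla, Mgl2, Irf4, H2-Aa and Mki67 lay higher in all day 14 libraries than in any day 4 library, Arg1, Nos2, Bnip3, Vegfa, Vcan and Col3a1 lay lower, and S100a9 overlapped.

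Of the genes of the 3 sort markers, Ptprc (CD45) and Emr1 (F4/80, now Adgre1) were slightly higher at day 14 and Itgam (CD11b) slightly lower. Ptprc rose from 1090 ± 90.1 to 1420 ± 74.4 CPM (adjusted p = 0.0074) and Emr1 from 1050 ± 54.3 to 1360 ± 109 CPM (adjusted p = 0.00914). Itgam fell from 1640 ± 166 to 1200 ± 73.5 CPM (adjusted p = 0.0051). In the list of 10 macrophage and sort markers, these 2 genes rose and 3 fell, with the same counts adjusted over the list alone. The other 2 that fell were Fcgr1, a high-affinity antibody receptor (2.15-fold lower), and Cd68, a lysosomal glycoprotein (1.38-fold lower). Lyz2, the macrophage lysozyme, was at 10000 ± 524 and 10700 ± 899 CPM. As a list, they were not called by limma's camera (adjusted p = 0.568). In the 6 shallower libraries, the log2 fold changes of Ptprc, Emr1 and Itgam went from 0.38 ± 0.08, 0.37 ± 0.08 and -0.45 ± 0.09 to 0.27 ± 0.10, 0.33 ± 0.11 and -0.47 ± 0.13, and with these larger standard errors they did not pass (adjusted p = 0.162, 0.122 and 0.0648).

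Most tested genes that cells induce at low oxygen, and of the glycolytic enzymes, were lower at day 14. Of 20 hypoxia-induced genes tested, 15 fell, 0 rose and 5 did not pass (16 fell adjusted over the list alone), with a median log2 fold change of -1.36. Vegfa, the main growth factor for blood vessels, fell from 741 ± 116 to 310 ± 45.7 CPM. Bnip3, a mitophagy receptor, fell 4.12-fold, and Pdk1, a kinase that restrains pyruvate entry into mitochondria, fell 3.06-fold. Of 18 glycolysis genes, 10 fell and 0 rose (12 fell adjusted over the list alone, and 12 with the 2 members beyond the break taken from the 8 other libraries). Tpi1, Pgam1 and Gapdh fell 2.58-fold, 2.51-fold and 2.15-fold. Pkm, the pyruvate kinase and the most abundant member, lies beyond the break and was at 1030 ± 196 CPM at day 4 and 468 ± 96.9 CPM at day 14 (n = 4 and 4, adjusted p = 0.000684). Camera called both lists lower (adjusted p = 3.57e-10 and 8.47e-07). With an estimated correlation, the calls were lost (adjusted p = 0.133 and 0.236). The mean log2 CPM of fibroblast markers differed by -0.90 between day 14 and day 4 in the same libraries.

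Some genes of mitochondrial energy metabolism fell. Of 22 genes of the TCA cycle and pyruvate dehydrogenase, 6 fell and 0 rose (6 fell adjusted over the list alone), among them Sdhb of succinate dehydrogenase (64.1 ± 2.39 to 49.5 ± 3.41 CPM) and the malate dehydrogenase gene Mdh2 (1.33-fold lower). Of 68 nuclear-encoded respiratory chain genes, 9 fell and 1 rose, Ndufa6 (8 and 1 adjusted over the list alone, and 10 and 1 with the members beyond the break taken from the 8 other libraries). The share of this list that was called lay below the 25.5% over all genes tested. The complex I gene Ndufb9 fell 1.27-fold, while the ATP synthase gene Atp5b was at 559 ± 31.4 and 527 ± 23.0 CPM. Camera called both lists lower (adjusted p = 0.0111 and 0.00306), with median log2 fold changes of -0.16 and -0.13 where members beyond the break were taken from the 8 other libraries (-0.23 and -0.15 with all 9). Without these members, both lists were still called lower. These calls were lost with an estimated correlation (adjusted p = 0.327 and 0.349). Of 18 fatty acid oxidation genes, the acyl-CoA dehydrogenase gene Acadm and Decr1 rose and the thiolase gene Acaa2 fell (2 rose and 4 fell adjusted over the list alone). Slc25a20, a carnitine carrier beyond the break, also fell in the 8 other libraries (log2 fold change -0.54), and the list was not called (adjusted p = 0.32) except as lower with the fibroblast score (adjusted p = 0.0418). Upper-quartile scaling ended the call of Acaa2 (adjusted p = 0.081). Cpt1a, the carnitine transferase that admits fatty acids to mitochondria, was 1.17-fold lower with an adjusted p of 0.0528, and it passed in 6 other fits, among them that without day 4 replicate 2 (adjusted p = 0.0218).

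Some genes of lipid handling fell, and a few of cholesterol synthesis rose. Of 18 lipid handling and foam-cell genes, 8 fell and 1 rose (9 and 2 adjusted over the list alone). The fatty acid-binding protein gene Fabp5 fell 2.16-fold and Nr1h3, the oxysterol receptor LXR alpha, 1.87-fold. Lpl, lipoprotein lipase, was the member that rose (2.41-fold), and the cholesterol exporter gene Abca1 was at 1900 ± 316 and 1640 ± 269 CPM. Camera called the list lower (adjusted p = 0.0015, and adjusted p = 0.281 with an estimated correlation). Of 18 cholesterol synthesis genes, 4 rose and 0 fell (4 adjusted over the list alone), among them Idi1, Cyp51 and Insig1, and in the 8 other libraries also Sc5d, which lies beyond the break. The share of this list called, counting both directions, was near the 25.5% over all genes tested. Idi1 of the isoprenoid steps rose 2.32-fold and Cyp51, which removes a methyl group from lanosterol, 1.49-fold. The list was called higher (adjusted p = 0.0373, and adjusted p = 0.236 with an estimated correlation). Its call was also lost without day 4 replicate 3 (adjusted p = 0.0802), without day 14 replicate 3 (adjusted p = 0.0713), and under upper-quartile scaling, total counts or the library size covariate (adjusted p = 0.07, 0.0597 and 0.102).

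Genes induced by IL-4 split into a larger group that rose and a smaller one that fell. Of 19 tested, 12 rose and 4 fell, with the same counts adjusted over the list alone. Mgl2, a C-type lectin, rose from 69.6 ± 15.1 to 418 ± 40.0 CPM, and Irf4, a transcription factor of IL-4-activated macrophages and dendritic cells, from 45.9 ± 6.71 to 261 ± 35.4 CPM. The mannose receptor gene Mrc1 rose 1.73-fold to 4520 ± 404 CPM. The members that fell were Arg1, the chitinase-like gene Chil3, the receptor subunit gene Il4ra and the transcription factor gene Tfec. Camera called the list higher (adjusted p = 0.00013, and adjusted p = 0.236 with an estimated correlation). In the same comparison, 7 of 11 dendritic cell markers and 3 of 5 eosinophil markers rose and 0 fell. With genes beyond the break taken from the 8 other libraries, 8 of 11 and 4 of 5 rose.

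Most tested genes of the MHC class II pathway, which presents peptides to CD4 T cells, rose. Of 15 genes of MHC class II antigen presentation, 11 rose and 2 fell (12 and 2 adjusted over the list alone). The antigen-presenting chain gene H2-Aa rose from 2080 ± 80.1 to 4360 ± 386 CPM and the invariant chain gene Cd74 from 4020 ± 361 to 8220 ± 776 CPM. H2-DMb2, a peptide-loading chain, rose 6.37-fold to 13.6 ± 2.12 CPM. The 2 that fell were Ctss and Ifi30, lysosomal enzymes that process antigen. Camera called the list higher (adjusted p = 2.88e-06, and adjusted p = 0.236 with an estimated correlation). In the same comparison, 7 of 11 dendritic cell markers rose, and 8 of 11 with the member beyond the break taken from the 8 other libraries.

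Inflammatory cytokine and chemokine genes went both ways. Of 20 tested, 4 rose (Il12b, Cxcl10, Ccl5 and Ccl7) and 2 fell (Nos2 and Ptgs2), with the same counts adjusted over the list alone. Il12b, a subunit of IL-12 and IL-23, rose from 0.988 ± 0.477 to 6.65 ± 1.64 CPM and the chemokine gene Cxcl10 rose 1.91-fold. Il1b, the gene of interleukin-1 beta, was at 2040 ± 743 and 1460 ± 423 CPM and did not pass (adjusted p = 0.213). Camera did not call the list (adjusted p = 0.663, direction up), while its median and mean log2 fold changes were -0.10 and -0.14. The neutrophil marker S100a9 varied between libraries of the same day, with 907 CPM in day 4 replicate 1 against 263 to 325 CPM in the others and with 67.9 to 821 CPM at day 14, the highest in replicate 3.

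Part of the interferon-stimulated genes and of the genes of recruited monocytes fell. Of 23 type I interferon-stimulated genes, 10 fell, 12 did not pass and 1 rose, Oasl1 (11 and 1 adjusted over the list alone). Irf7, a master regulator of type I interferon responses, fell 2.99-fold and Oasl2 fell 2.01-fold, while Oas2 was at 174 ± 38.4 and 148 ± 9.58 CPM. Of 18 recruited monocyte genes, 10 fell, 8 did not pass and 0 rose (11 fell adjusted over the list alone). Vcan, the proteoglycan versican, fell 3.18-fold, Plac8 2.23-fold and Thbs1, the matricellular protein thrombospondin 1, from 15400 ± 3450 to 7400 ± 1940 CPM. With the fibroblast score as a covariate, Vcan went from a log2 fold change of -1.67 ± 0.20 to -1.38 ± 0.34 and Thbs1 from -1.06 ± 0.20 to -0.82 ± 0.36, and with these larger standard errors they did not pass (adjusted p = 0.0666 and 0.271). Ccr2, the monocyte chemokine receptor, lies beyond the break and rose 1.41-fold in the 8 other libraries (adjusted p = 0.0238). Camera called both lists lower (adjusted p = 6.1e-05 and 1.25e-05). The calls were lost with an estimated correlation (adjusted p = 0.349 and 0.236).

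Genes of tissue-resident macrophages showed no common direction. Of 24 tested, 5 rose and 2 fell, with the same counts adjusted over the list alone. The phosphatidylserine receptor gene Timd4 rose 2.55-fold to 6.18 ± 1.35 CPM and Igfbp4 rose 1.52-fold, together with Lyve1, F13a1 and Sepp1, and in the 8 other libraries Cx3cr1, which lies beyond the break. The chemokine gene Pf4 fell 1.56-fold, and the other member that fell was the efferocytosis receptor gene Mertk. Apoe, apolipoprotein E, was at 8000 ± 537 and 7480 ± 584 CPM. Camera did not call the list (adjusted p = 0.32), but it was called higher with the library size covariate (adjusted p = 0.0491) and among the 6 shallower libraries (adjusted p = 0.00245).

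Over the cell cycle list, the genes that passed were higher at day 14. Of 30 tested, 16 rose, 14 did not pass and 0 fell (18 and 1 adjusted over the list alone). The proliferation marker Mki67 rose from 99.4 ± 11.4 to 238 ± 32.5 CPM and Top2a, a topoisomerase of dividing cells, from 46.3 ± 7.37 to 92.6 ± 13.1 CPM. The kinase gene Aurkb of the mitotic spindle rose 1.69-fold, and Ccnb2, which lies beyond the break, rose in the 8 other libraries (log2 fold change 0.47). Camera called the list higher (adjusted p = 1.26e-06, and adjusted p = 0.236 with an estimated correlation).

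Several matrix-degrading enzymes fell. Of 23 matrix proteases and their inhibitors, 8 fell and 3 rose (9 and 5 adjusted over the list alone). Ctsk, the collagen-degrading cathepsin K, fell from 442 ± 121 to 65.8 ± 9.40 CPM, the membrane metalloprotease gene Mmp14 fell 3.32-fold and the lysosomal protease gene Ctsl 2.24-fold. The 3 that rose were Mmp19, the urokinase gene Plau and the inhibitor gene Timp3. Timp1, an inhibitor beyond the break, fell in the 8 other libraries (log2 fold change -1.60). Camera called the list lower (adjusted p = 0.0122, and adjusted p = 0.347 with an estimated correlation). Its call ended without day 4 replicate 1 (adjusted p = 0.05, just above the threshold) and with the fibroblast score as a covariate (adjusted p = 0.253), and the mean log2 CPM of fibroblast markers differed by -0.90 between the days. Of 18 secreted growth factors, 6 fell and 2 rose, Igf1 and Pdgfc (7 and 5 adjusted over the list alone). Igf1, insulin-like growth factor 1, rose from 213 ± 29.1 to 461 ± 78.3 CPM, the epidermal growth factor receptor ligand gene Ereg fell 7.63-fold and Lif, a cytokine of the IL-6 family, 2.39-fold. With the fibroblast score, Ereg went from -2.93 ± 0.50 to -1.89 ± 0.80 and did not pass (adjusted p = 0.28), nor did Igf1 (1.12 ± 0.15 to 1.02 ± 0.27, adjusted p = 0.0779) and Lif (-1.26 ± 0.16 to -0.94 ± 0.26, adjusted p = 0.0879). This list was not called (adjusted p = 0.663, direction down, with a median log2 fold change of 0.01 and a mean of -0.35).

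Part of the oxidative stress genes fell, and part of the early response and dissociation stress genes rose. Of 18 genes of the oxidative stress response and pentose phosphate pathway, 7 fell, 11 did not pass and 0 rose (8 fell adjusted over the list alone). Hmox1, the heme-degrading enzyme, fell from 2180 ± 259 to 1020 ± 175 CPM and Gclm of glutathione synthesis fell 2.32-fold. Camera called the list lower (adjusted p = 0.000922, and adjusted p = 0.283 with an estimated correlation). Of 23 early response and dissociation stress genes, 7 rose, 15 did not pass and 1 fell, Ier3 (9 and 2 adjusted over the list alone). The chaperone genes Hspa1b and Hsph1 rose 3.22-fold and 3.01-fold, to 1470 ± 231 and 394 ± 108 CPM, and Hspa1a, which shares most of its sequence with Hspa1b so that their reads may be split, rose 2.61-fold. With the fibroblast score, Hspa1b went from 1.69 ± 0.22 to 1.62 ± 0.40 and Hsph1 from 1.59 ± 0.19 to 1.45 ± 0.35, and neither passed (adjusted p = 0.0666 and 0.0533). Fos, an immediate early gene, was at 1520 ± 321 and 1470 ± 262 CPM. The list was called higher (adjusted p = 0.011, and adjusted p = 0.444 with an estimated correlation), and not without day 14 replicate 3 (adjusted p = 0.0768). Of 17 genes of the unfolded protein response, Atf4, Herpud1 and Hsp90b1 rose and Asns, asparagine synthetase, fell 3.30-fold (3 and 1 adjusted over the list alone). The share of this list called was near the 25.5% over all genes tested. Hspa5, the main chaperone of the endoplasmic reticulum, was at 1750 ± 151 and 1860 ± 125 CPM, and the list was not called (adjusted p = 0.434, direction up, with a median log2 fold change of 0.09 and a mean of -0.08).

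**Figure D3:**
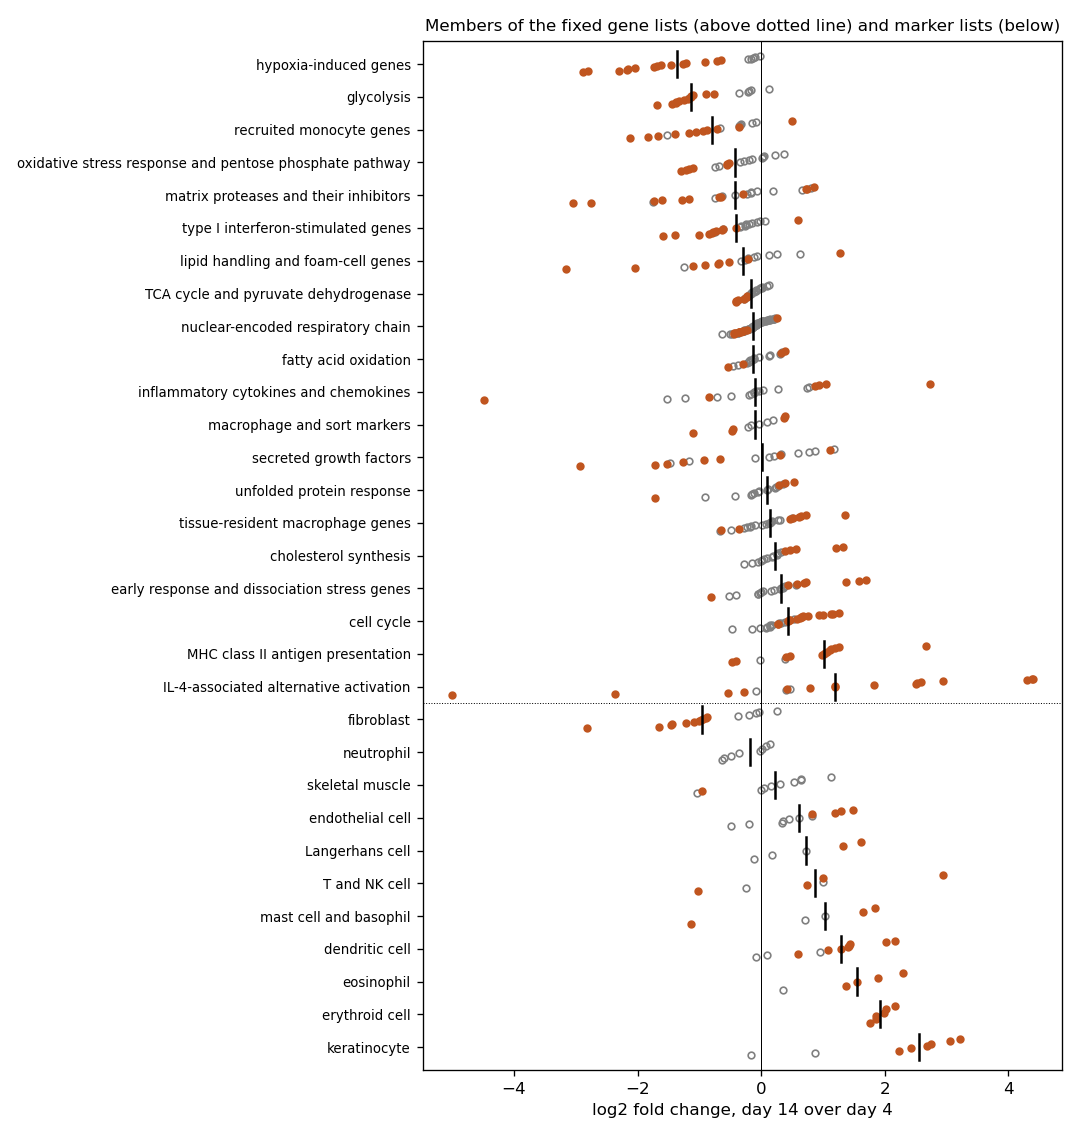
Log2 fold change, day 14 over day 4 (horizontal axis), of each tested member of the 20 gene lists (above the dotted line) and 11 cell type marker lists (below it), with genes beyond the break taken from the 8 other libraries. Filled points passed the edgeR test, open points did not, and black bars mark medians, which lay at -1.36 for hypoxia-induced genes, 1.20 for IL-4-associated genes and -0.96 for fibroblast markers.

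Markers of other cell types were detected in the sorted cells, and many of those of fibroblasts, keratinocytes and erythroid cells differed between the days. Of 16 fibroblast markers, 11 fell, with 0 rising (11 fell adjusted over the list alone). The collagen genes Col3a1 and Col1a2 fell from 5950 ± 1800 to 3030 ± 628 CPM and from 2890 ± 1040 to 1360 ± 351 CPM. Camera called these markers lower (adjusted p = 0.000208, and adjusted p = 0.439 with an estimated correlation). Of 8 keratinocyte markers, 6 rose and 0 fell (6 adjusted over the list alone), all at low levels, with the desmosome gene Perp at 0.685 ± 0.169 and 5.72 ± 1.15 CPM and Sfn at 3.74 ± 0.778 and 3.32 ± 0.49 CPM. All 6 erythroid markers rose (6 adjusted over the list alone), with Hba-a1 at 1.97 ± 1.07 and 8.93 ± 2.19 CPM and Hbb-b1 4.04-fold higher at 12.1 ± 3.18 CPM, both members of families with near-identical copies. The keratinocyte and erythroid lists were called higher (adjusted p = 0.000656 and 0.000446). With an estimated correlation, both calls were lost (adjusted p = 0.236 and 0.281).

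Several markers of dendritic cells, eosinophils and lymphocytes rose. Of 11 dendritic cell markers, 7 rose and 0 fell (7 adjusted over the list alone). Cd209a, a lectin of monocyte-derived dendritic cells, rose from 51.5 ± 6.38 to 136 ± 19.8 CPM and Ccr7, the homing receptor of migrating dendritic cells, from 45.2 ± 15.2 to 96.2 ± 19.2 CPM. Xcr1, a chemokine receptor of these cells beyond the break, rose in the 8 other libraries (log2 fold change 1.29). Of 5 eosinophil markers, 3 rose and 0 fell (3 adjusted over the list alone): Siglec5 (now Siglecf), Prg2 and Il5ra. The granule protein gene Prg2 rose 2.93-fold to 12.9 ± 2.25 CPM, and Ccr3, which lies beyond the break, was at 8.74 ± 1.42 and 32.5 ± 10.5 CPM (n = 4 and 4, adjusted p = 0.000222). Of 6 T and NK cell markers, 3 rose and 0 fell (3 adjusted over the list alone): Cd2, Cd4 and Il7r. Thy1, which lies beyond the break and marks other cells too, fell in the 8 other libraries (log2 fold change -1.02, adjusted p = 0.00704). Cd4 rose 1.68-fold. Il7r was 2-fold higher with an adjusted p of 0.0479, and did not pass without day 4 replicates 2, 3 or 4 (adjusted p = 0.0713, 0.114 and 0.124) or day 14 replicates 1, 2 or 4 (adjusted p = 0.0969, 0.0788 and 0.0846), with no low-count filter (adjusted p = 0.0671) or with the library size covariate (adjusted p = 0.105). Camera called the dendritic cell, eosinophil and T and NK cell lists higher (adjusted p = 0.000208, 0.0115 and 0.0344). With an estimated correlation, the calls were lost (adjusted p = 0.236, 0.239 and 0.236), and the T and NK cell call also ended without day 14 replicate 5 (adjusted p = 0.0851), under upper-quartile scaling (adjusted p = 0.0688) and with no low-count filter (adjusted p = 0.0773). The eosinophil call ended with the fibroblast score (adjusted p = 0.0811), where Prg2 went from a log2 fold change of 1.55 ± 0.20 to 1.19 ± 0.31 and Ccr3 from 1.90 ± 0.23 to 1.45 ± 0.47.

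The remaining markers gave weaker or no calls. Of 8 neutrophil markers, 0 passed in either direction with edgeR (0 adjusted over the list alone), where S100a9 was at 449 ± 306 and 296 ± 316 CPM and Csf3r, the receptor of a neutrophil growth factor, at 166 ± 33.2 and 168 ± 98.1 CPM. The log2 fold change of S100a9 was -0.60 ± 0.83, -1.46 without day 14 replicate 3 and 0.00 without day 4 replicate 1. In the list of 5 mast cell and basophil markers, the protease genes Cpa3 (3.15-fold) and Mcpt4 rose and the receptor gene Kit fell 2.21-fold (2 and 1 adjusted over the list alone), and in that of 5 Langerhans cell markers, Cd207 (2.49-fold) and Epcam rose (3 adjusted over the list alone) while Mfge8 was at 28.7 ± 2.21 and 26.6 ± 6.39 CPM. These 3 lists were not called (adjusted p = 0.434, 0.208 and 0.131 in the same order), but the mast cell list was called higher without day 14 replicate 4 (adjusted p = 0.0268) and with no low-count filter (adjusted p = 0.0274), and the Langerhans cell list with fry (adjusted p = 0.0205) and with the fibroblast score (adjusted p = 0.0245). With that score, Kit went from a log2 fold change of -1.14 ± 0.26 to -0.23 ± 0.33 and did not pass (adjusted p = 0.787). Of 11 endothelial markers, 4 rose (4 adjusted over the list alone): Tek, Emcn, Cldn5 and Flt1. Pecam1 was at 22.3 ± 1.92 and 19.6 ± 4.28 CPM and Cdh5 at 7.79 ± 1.52 and 9.88 ± 3.32 CPM. The endothelial list was just called (adjusted p = 0.0492, and adjusted p = 0.529 with an estimated correlation), and the call ended without day 4 replicates 1, 3 or 4 (adjusted p = 0.0556, 0.0529 and 0.0509) or day 14 replicates 1, 3 or 5 (adjusted p = 0.0524, 0.193 and 0.0714). It also ended with upper-quartile scaling, total counts, the strict filter, the library size covariate, fry and a prior count of 0.5 (adjusted p = 0.102, 0.0653, 0.273, 0.0622, 0.0878 and 0.0511). Of 10 skeletal muscle markers, Des fell (0 adjusted over the list alone), Acta1 was at 6.29 ± 4.56 and 6.63 ± 3.05 CPM, Mylpf at 2.38 ± 1.20 and 3.81 ± 1.55 CPM, and the list was not called (adjusted p = 0.482), though it was higher in the 6 shallower libraries (adjusted p = 0.00341). Both tested B cell markers rose, Igj and Cd79b, the latter 1.89-fold (2 adjusted over the list alone), and of 2 tested adipocyte markers Cfd fell 3.50-fold (2 fell adjusted over the list alone). These last 2 lists were too short for a list test.

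Over all lists, camera called 5 gene lists higher and 9 lower of 20 tested, and 6 marker lists higher and 1 lower of 11 tested. With an estimated correlation per list (median 0.232), 0 of the 31 lists passed, and 4 had an unadjusted p under 0.05. With fry, which tests whether the genes of a list move one way without comparing them with other genes, 14 gene lists and 7 marker lists passed, the latter with the Langerhans cell list in place of the endothelial one.

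The fibroblast score ended the calls of 40 of the 83 called genes followed. These were Igj, Arg1, Nos2, Ptges, Cxcl5, Ptprc, Itgam, Emr1, Pkm, Sdhb, Ndufb9, Acadm, Acaa2, Cxcl10, Mrc1, Timd4, Igfbp4, Vcan, Thbs1, Igf1, Lif, Ereg, Gclm, Asns, Atf4, Hsph1, Hspa1b, Ccr3, Prg2, Kit, Cpa3, Il7r, Cd4, Cd79b, Cd207, Cfd, Hbb-b1, Hba-a1 and the score's own members Col3a1 and Col1a2. Ccr7 went the other way, from 1.09 ± 0.22 to 1.8 ± 0.27 with the score. The 17 that did not pass in the 6 shallower libraries included Arg1, Nos2, the genes of the 3 sort markers, Sdhb, Acadm, Acaa2, Cxcl10, Atf4, Cd68, Il7r, Ccr7, Cd207, Cfd and Hbb-b1. Kit went from -1.14 ± 0.26 to -1.57 ± 0.27 there and passed.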

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

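Apart from the counts of splits, the tests given here were chosen after the results, or values of their genes per library, had been seen, and the condition on dendritic cell markers was tightened after its count was known. Of 272 groups of 4 or 5 values examined, 16 held a library far from the others of its day, where chance gives about 1 in 20.

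In day 14 replicate 5, 0.0254% of the counts lay in the genes beyond the break, Aplp2 included, against 7.49% to 7.93% in the other libraries of its day. Shallow sequencing is argued against by the 1175 genes at 0 there but with a count in each of the 8 other libraries, whose median expected count was 268. An end of counting partway along chromosome 9, as in a file that was truncated, may account for it, since 483 of 483 well-counted genes beyond that position were at 0. The authors' normalized table holds values other than 1 for 186 of these genes in this library. No biological explanation was tested.

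Hypoxia-induced and glycolysis genes were lower together at day 14, with a difference of -1.14 ± 0.095 (SE) in mean log2 CPM over 33 members outside the break. If fewer fibroblasts in the late sorts were the whole cause, the difference would be near 0 at equal fibroblast marker RNA. With that score in a linear model it was -1.12 ± 0.18. However, the scores of the 2 days did not overlap (0.11 to 1.12 at day 4 and -0.64 to -0.06 at day 14). No libraries of the 2 days had equal fibroblast marker RNA, so the model cannot decide, and fewer fibroblasts stay open. With the neutrophil marker score the difference was -1.07 ± 0.048, and among the 6 shallower libraries -1.16 ± 0.157, which argues against neutrophil RNA and depth as the whole cause. With the fibroblast score in the test of each gene, 470 of the 3407 called genes kept their call, and for the 33 members together the standard error grew from 0.095 to 0.18. Time after injury, which the design names, stays open as an untested biological explanation that may act within macrophages.

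Of 19 IL-4-associated genes, 12 rose and 4 fell, in the same libraries in which 7 of 11 dendritic cell markers and 3 of 5 eosinophil markers rose. With genes beyond the break taken from the 8 other libraries, 8 of 11 and 4 of 5 of these markers rose. The test assumed that more conventional dendritic cells would raise the listed markers alike. The median over the 10 markers outside the break was 1.24. Of those at 5 CPM or more, 3 (Flt3, Fscn1 and Kmo) lay below it by more than 2 standard errors, with Flt3 at 0.10 ± 0.21. The list mixes markers of different dendritic cells, such as Cd209a of monocyte-derived and Ccr7 of migrating ones, which need not rise alike. Kmo still passed (0.60, adjusted p = 0.0164), and Cd209a and Ccr7 rose from higher day 4 levels (51.5 to 136 CPM and 45.2 to 96.2 CPM, against 15.3 to 17.6 CPM for the 3 lower markers at day 4). With some markers rising and others not, a larger share of conventional dendritic cells cannot be told apart from a change within macrophages. The 4 eosinophil markers outside the break had a median log2 fold change of 1.46 (1.55 over all 5). The 12 IL-4-associated genes that rose had a median of 2.52, but they were picked by their rise. The median over all 19 was 1.20. The comparison therefore cannot decide, and eosinophils stay open as a candidate source of the rise or part of it. Time after injury stays open, untested.

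For the number of genes called, a random division of these 9 libraries is argued against. Among 100 of the 126 splits into 4 and 5, only the real split reached 3407 genes (1 of 100). The highest other had 2408, and it put day 14 replicate 3 with the day 4 libraries. The labels do not say that the libraries came from separate animals, so these splits cannot exclude chance differences between animals. For genes with a 2-fold change, the real split gave 1074 and the highest other 589 (1 of 100). For gene lists called, 3 of 100 splits reached the real 14, the real one included, and the highest other also had 14. This met the rule set before, under 5% of splits. The splits that tied lay close to the real one: 1 put day 14 replicate 4 with the day 4 libraries, and 1 exchanged day 4 replicate 4 for day 14 replicate 2. Chance is still not called excluded for the gene lists, since other splits called as many. The splits other than the real one called a median of 5 gene lists but 0 genes.

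Several single values stood apart from those of the same day, at about the rate that chance gives. Day 14 replicate 1 had the most counts of its day (50.4 M), with the lowest Hba-a1 (5.04 CPM against 9.59 to 10.2 CPM) and the lowest mean log2 CPM of erythroid markers, Hba-a1 among them (1.72 against 2.47 to 2.71). In day 4 replicate 1, Ptges (78.2 CPM against 30.4 to 31.9 CPM), Il1b (3150 CPM against 1600 to 1790 CPM) and S100a9 (907 CPM against 263 to 325 CPM) were high. In day 4 replicate 2, Idi1 (20.1 CPM), Ccr7 (67.9 CPM) and the mean log2 CPM of keratinocyte markers (-0.24) were high and Cd68 (465 CPM) was low. Day 14 replicate 3 was high in Nos2 (9.48 CPM against 0.646 to 2.79 CPM) and Irf7 (113 CPM against 62.8 to 75.2 CPM). Vegfa was high in day 14 replicate 4 (391 CPM), Cd207 in day 14 replicate 2 (11.5 CPM), and Pecam1 was low in day 4 replicate 3 (19.5 CPM).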

How the results depend on the processing

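The depth subsets, the marker scores and the treatments of genes beyond the break were chosen after seeing the data. The 83 called genes among the 101 followed kept their direction in every fit where they were tested, and outside these later alternatives Il7r and Acaa2 lost their calls. All fits reuse the same libraries, so a kept direction is no independent check. Without 1 library each, 1235 to 1967 genes were called higher, 1160 to 2116 lower, 495 to 610 at least 2-fold higher and 425 to 632 at least 2-fold lower, with 3 to 5 gene lists higher and 8 to 9 lower. The count of 3 was without day 14 replicate 3. Upper-quartile scaling called 1089 genes lower. The strict filter, with fewer genes tested (9917), called 243 at least 2-fold higher and 281 lower. Camera with an estimated correlation called 0 gene lists higher and 0 lower (lowest adjusted p = 0.133, 4 lists at an unadjusted p under 0.05), while fry called 5 and 9.

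The 6 shallower libraries gave 668 genes higher and 666 lower. The 3 deeper ones, with 1 day 14 library assumed to vary like the day 4 ones, say nothing about stability and gave 2860 and 2806, with 803 at least 2-fold lower, and 3 gene lists higher and 5 lower. With the fibroblast score, 307 genes were higher and 197 lower, 257 and 117 of them by at least 2-fold, and of the 3407 genes called without it 3360 kept their direction and 470 their call. For these and the reversals below, the cause was not tested.

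The fibroblast list reversed under its own score (adjusted p = 0.793). The other results that reversed had not passed before. The inflammatory list did so with the library size covariate and in the shallower libraries (0.773 and 0.491), the resident list in the deeper libraries and with the fibroblast score (0.854 and 0.416), and the muscle list likewise (0.0417 and 0.855). The growth factor list did so with the strict filter and the fibroblast score (0.77 and 0.855) and ranged from 0.517 to 0.972 without 1 library each. On the log2 scale, Abca1 was 0.17 in the deeper libraries, and Oas2 0.03 and Hspa5 -0.04 in the shallower. Fos was 0.01 with upper-quartile scaling, 0.08 with the size covariate, 0.24 in the shallower libraries and -0.18 to 0.04 without 1 library each. Csf3r was -0.12 with voom, -0.01 without a filter, -0.20 with the size covariate, -0.59 in the deeper libraries and -0.43 to 0.15 without 1 library each. Acta1 was -0.13 with voom, -1.59 in the deeper libraries, 1.11 in the shallower, -0.42 with the fibroblast score and -0.24 to 0.67 without 1 library each. Mylpf was -0.69 in the deeper libraries and 1.51 in the shallower, where it passed. With the fibroblast score, Lyz2 was -0.08, S100a9 0.33, Mfge8 0.33 and Pecam1 0.01.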
